A study of Mus musculus with 8 samples.

How the data were processed

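Gene expression was measured with Affymetrix Mouse Gene 2.0 ST arrays in CD4+CD25+ lymphocytes, the T cell fraction in which regulatory T cells are concentrated. Per the labels' protocols, the cells were sorted by flow cytometry from para-aortic lymph nodes, which drain the uterus, of pregnant mice at day 9.5 post coitus. The groups were 4 arrays labelled Il10-/- and 4 arrays labelled Il10+/+. Each array received a pool of RNA from 2 to 4 mice, so the replicates were separate pools of animals, per the series' design text. The Il10+/+ mice were C57BL/6 and the Il10-/- mice had been backcrossed to that strain. Per the labels' protocols, the Il10-/- mice drank water with oxytetracycline at 2 mg/ml against colitis, and no such treatment is stated for the Il10+/+ mice, so the antibiotic and the genotype cannot be separated.

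The deposited log2 expression values were made by the authors with the robust multi-array average (RMA) background correction, a GC content correction and averaging of the probes of each probe set in Partek Genomics Suite, per the series' design text. The submitters' processing notes also name Affymetrix Expression Console. Versions of these programs and the genome build behind the probe sets are not given in the sources used here, so no coordinates are printed. RNA was amplified with the Ovation PicoSL system before labelling with biotin.

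The value table used here held 16378 probe sets. The platform annotation named 7358 of them with 1 gene, 456 with several genes and 8564 with none. Symbols were updated through Entrez gene identifiers to the RefSeq gene table of assembly GRCm38.p6, where 7310 of the probe sets with 1 gene matched, and that table was otherwise used only for which genes neighbour each other. Where a gene had several probe sets, which was so for 284 genes, the one with the highest mean over the 8 arrays was taken. This left 6986 genes, without a filter on signal level. Of the 6942 genes with a chromosome, 6913 (99.6%) lay on chromosomes 1 and 10 to 15. Gene lists were therefore measured only in part, and genes outside the table were not analysed here.

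The arrays labelled Il10-/- were compared with the arrays labelled Il10+/+ in a linear model per gene with limma 3.58.1 (lmFit and eBayes, without trend or robust settings) in R 4.3.3. Differences are log2 values, Il10-/- minus Il10+/+ as labelled, with their standard error (SE) and moderated p-values adjusted by the Benjamini-Hochberg method over all 6986 genes, at a threshold of 0.05. For 7 genes an exact two-sided permutation test over the 70 assignments of 4 and 4 arrays was added, which cannot give a p below 0.0286. The choice of Efcab2, Ctse, Ifng and Il17a for that test was made after their values were seen.

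Gene lists were tested with limma's camera at the preset correlation of 0.01, adjusted over the 24 lists with at least 5 measured genes, then with an estimated correlation and with fry, which asks whether a list's genes move on balance one way or in either direction. The lists covered Treg identity, effector Treg, suppressive mediators, naive and central T cells, Th1, Th17, Th2, type I interferon response, interferon gamma response, T cell receptor (TCR) activation, cell cycle, apoptosis regulators, chemokine receptors and homing, glycolysis, nuclear OXPHOS, mitochondrial stress and ATF4 targets, cholesterol synthesis, heat shock and dissociation stress, ribosomal proteins, T cell lineage, B cell, macrophage and monocyte, neutrophil and granulocyte, and stroma. A further 8 of the 32 lists had fewer than 5 measured genes and were not tested: follicular helper T cell, IL10 receptor and STAT3 pathway, mitochondrially encoded genes, plasma cell, antigen presentation by class II, dendritic cell, CD8 T cell and NK cell, and erythroid and platelet. Together the lists named 618 genes, 179 of which were measured. The error of a mean over list members came from the spread of the members' mean between arrays of a group. Genes within 10 Mb on either side of Il10 were compared with all other genes by Fisher's exact test, two-sided, with Il10 left out.

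The groups, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named Il10, Il10ra, Il10rb, Foxp3, Il2ra, Ctla4, Cd4, Cd3e and Ikzf2 where measured, and up to 12 genes per direction with the largest difference among those past the threshold whose groups did not overlap. Where fewer than 10 qualified, it was filled to 10 with the genes of smallest unadjusted p among those at unadjusted p under 0.05 with a log2 difference of at least 0.58 and no overlap. It also took the called members of each list, at most 4, filled to 2 with the members of next smallest p, and the called genes near Il10. Unnamed gene models and receptor or immunoglobulin gene segments were left out of the filled part. Other genes in the text were chosen after their values were seen.

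The alternatives were other normalizations between arrays, filters on dim genes, other variance models and array weights, the replicate number as a block, an equal-variance t-test, other choices of probe sets, other thresholds and windows, other list tests, and leaving out each array in turn. Leaving out 2 arrays that stood apart, the spread of each array as a covariate and leaving out Ctse near Il10 were added after seeing the data. The gene test was tested on simulated data for this comparison, in 20 simulations of 6986 genes with 200 changed. It recovered 41.9% of genes changed by 0.5 on the log2 scale, 89.7% of those changed by 1 and 99.2% of those changed by 2. Among its calls, 3.95% were false. With fewer changed genes than the 200 simulated, the adjustment is stricter, so these shares can overstate the recovery in the data, where 2 genes passed. A simulated shift of 0.5 in the cell cycle list was found in 20 of 20 simulations of the list test. In these simulations 1 list was called without a shift. The noise of each gene was drawn independently, so these counts do not cover lists whose members vary together. In the data the estimated correlation was 0.65 for the cell cycle list and 0.22 for the Th17 list. The number of arrays limits the precision of every comparison.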

Results

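Expression was profiled in CD4+CD25+ T cells, the fraction rich in Foxp3+ regulatory T cells (Treg), from the lymph nodes that drain the uterus at day 9.5 of mouse pregnancy. The comparison was between 4 arrays labelled Il10-/-, from mice without a functional gene for the anti-inflammatory cytokine interleukin 10, and 4 arrays labelled Il10+/+. It addressed how this T cell fraction of pregnancy differs without interleukin 10, in a study concerned with the stability of regulatory T cells. Each array held RNA from a separate pool of 2 to 4 mice. In all, 6986 genes were tested, 99.6% of those placed lying on chromosomes 1 and 10 to 15. Foxp3, Il2ra, Cd4, Cd3e, Il10ra and Il10rb were not analysed here. The share of Foxp3+ cells in each pool was therefore not measured. A difference in that share cannot be told apart from a change within Treg.

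The median log2 value of the tested genes lay between 6.97 and 7.12 in the 8 arrays. Across genes, which are not independent replicates, Pearson's r between arrays ranged from 0.974 to 0.993 over the 28 pairs. The arrays labelled Il10-/- replicate 2 and Il10+/+ replicate 4 stood apart from the rest. Their interquartile ranges were 2.15 and 2.17, against 2.32 to 2.58 in the other arrays, and their scores on the first principal component, which held 31.1% of the variance, were 16.6 and 17.8. With 1 such array in each group, this difference did not follow the genotype labels.

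**Figure D1:**
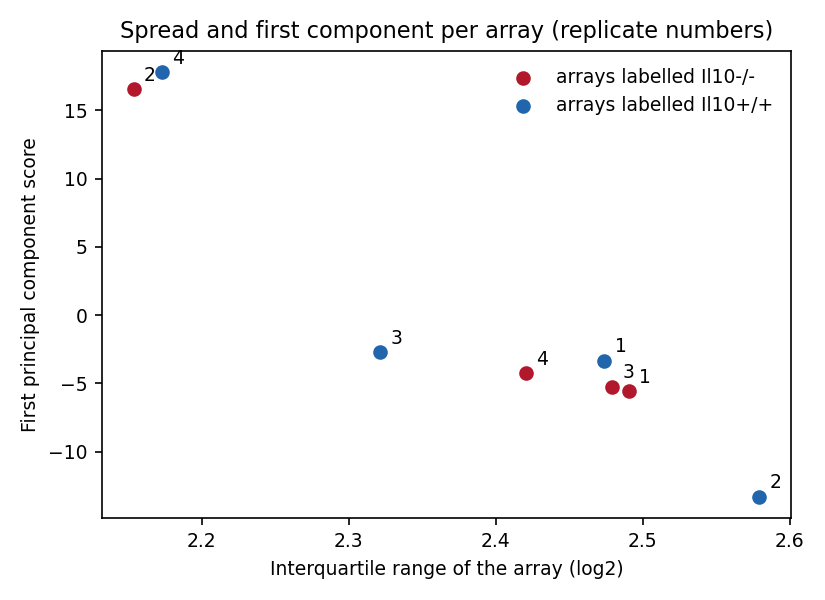
Interquartile range of the log2 values of each array (x axis) against its score on the first principal component (y axis), with the replicate number beside each point and colours for the groups as labelled. Il10-/- replicate 2 and Il10+/+ replicate 4 lie together at the upper left, with scores of 16.6 and 17.8.

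Il10, the gene disrupted in the mutant mice, gave a signal in every array, and the signal was stronger in the arrays labelled Il10-/-. Those arrays read 9.35, 8.65, 9.42 and 9.25 for replicates 1 to 4, and the arrays labelled Il10+/+ read 8.27, 8.51, 8.14 and 7.50. The means were 9.17 ± 0.35 and 8.10 ± 0.43 (SD, n = 4 each), a log2 difference of 1.06 (SE 0.22), or 2.09-fold, from probe set 17216990. The groups did not overlap, and the exact permutation test gave p = 0.0286, the smallest it allows. By limma, Il10, a gene fixed before the data were examined, had an unadjusted p of 0.000661. It did not pass limma's test over all genes (adjusted p = 0.405). This direction is the opposite of a lost transcript, but it does not by itself contradict the genotype labels. The mutated part of Il10 is not named in the sources used here, so a probe set that reads outside it checks no label. All directions given for the arrays labelled Il10-/- rest on those labels.

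Ctse, which encodes the endosomal aspartic protease cathepsin E, was the gene with the largest and clearest difference. It rose to 11.67 ± 0.12 in the arrays labelled Il10-/- from 8.83 ± 0.19 in those labelled Il10+/+ (SD, n = 4 each), a log2 difference of 2.84 (SE 0.12) or 7.16-fold. Efcab2, an EF-hand protein of the ciliary dynein regulatory complex, also rose, to 8.20 ± 0.37 from 6.85 ± 0.04 (SD, n = 4 each), a log2 difference of 1.35 (SE 0.16) or 2.56-fold. For both genes, on chromosome 1 and read by probe sets 17217035 and 17219988, all 4 arrays labelled Il10-/- lay above all 4 labelled Il10+/+. The Treg genes Ctla4, an inhibitory receptor, and Ikzf2, the transcription factor Helios, did not pass the test. Ctla4 measured 11.22 ± 0.23 against 11.32 ± 0.15, and Ikzf2 measured 11.35 ± 0.15 against 11.54 ± 0.15 (SD, n = 4 each), with exact permutation p = 0.571 and 0.143.

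Ctse (limma, adjusted p = 8.33e-07) and Efcab2 (adjusted p = 0.0201) were the 2 of 6986 genes past the threshold, and 0 genes fell. At an unadjusted p under 0.05, limma counted 334 genes, 223 higher and 111 lower, where chance alone would give 349. The groups did not overlap for 204 genes, or 2.92%, against 2.86% by chance. By an equal-variance test per gene with the same adjustment, Ctse alone passed and 0 genes were lower. Efcab2 also missed the threshold with either of Il10-/- replicates 1 or 2 left out (adjusted p = 0.136 and 0.115) and with Il10+/+ replicate 1, 2, 3 or 4 left out (0.101, 0.0889, 0.106 and 0.0581). Without Il10-/- replicate 3, 4 genes passed, Ctse, Efcab2, Hesx1 and the microRNA gene Mir3473c, and without both arrays that stood apart 1 gene passed, Ctse.

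**Figure D2:**
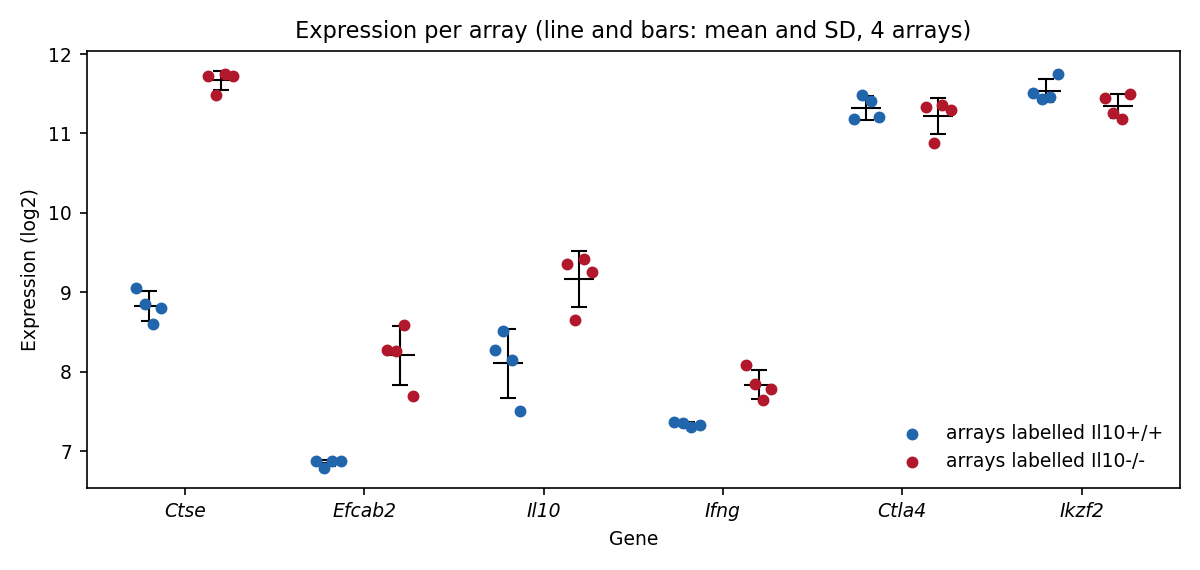
Log2 expression (y axis) of 6 genes in each array, with points for arrays, coloured by group as labelled, and black marks for the mean and SD of 4 arrays. Ctse, Efcab2, Il10 and Ifng separate the groups without overlap, while Ctla4 and Ikzf2 overlap.

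Several further genes lay higher in all 4 arrays labelled Il10-/- by at least 0.58 but did not pass the adjustment. Hesx1, a homeobox repressor, came closest with a log2 difference of 0.97 (adjusted p = 0.0752). Its signal was dim, with means of 6.39 in Il10-/- and 5.42 in Il10+/+. Tex35 differed by 0.83 (adjusted p = 0.171) and the Mediator subunit Med31 by 0.74 (adjusted p = 0.224). Ctla2a and Ctla2b, paralogous inhibitors of cysteine proteases whose separate signals are uncertain, differed by 0.80 and 1.10. The calcium pump gene Atp2b4 differed by 0.59 and Gch1, the first enzyme of tetrahydrobiopterin synthesis, by 0.62. In the other direction, Lad1, which encodes the anchoring filament protein ladinin, differed by -0.69 (adjusted p = 0.742; -0.45 without Il10+/+ replicate 1) and the pseudogene Pisd-ps1 by -0.67 (adjusted p = 0.650). Adjusted p-values of the remaining genes ran from 0.405 for Ctla2a to 0.667 for Gch1.

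Genes of cell division were higher as a group in the arrays labelled Il10-/-. Of 11 measured cell cycle genes, 9 had a positive difference, with a median of 0.43, led by the topoisomerase Top2a (0.61, SE 0.16) and the mitotic kinase Pbk (0.61, SE 0.18). Cdk1 differed by 0.60, Rrm2 by 0.43 and Cenpf by 0.47, whereas the replication genes Mcm6 and Tk1 differed by -0.23 and -0.08. The group passed camera with the preset correlation (adjusted p = 0.0123), but its members varied together between arrays, and with an estimated correlation it did not pass (adjusted p = 0.558, unadjusted p = 0.231). None of the 11 passed over all genes, and Top2a and Pbk passed when adjusted over the list alone. The adjusted p by camera was above the threshold without Il10-/- replicate 3 (0.0664) or 4 (0.105) and without Il10+/+ replicate 1 (0.0564) or 4 (0.231), and leaving out either of the last pair took the median to 0.28 and 0.24.

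Genes of interleukin 17-producing helper cells (Th17) were also higher as a group, in 6 of 6 measured members, with a median of 0.23. The receptor gene Il1r1 differed by 0.91 (SE 0.29). The cytokine gene Il17a differed by 0.57 (SE 0.21, exact permutation p = 0.0571), and by 0.37 without Il10+/+ replicate 3. Il17f followed at 0.25 and Il22 at 0.21. Il22 had means of 2.77 in the arrays labelled Il10-/- and 2.56 in those labelled Il10+/+. These lie near the lowest value of any probe set per array (2.07 to 2.25), so its direction carries little weight. Il17a (means 7.39 in Il10-/- and 6.82 in Il10+/+), Il17f (7.33 and 7.08) and Csf2 (7.42 and 7.28) lay near the arrays' medians. The red cell marker Slc4a1 read a similar 7.05 and 6.94. No detection call was used, so expression of these cytokine genes is not shown. The group passed camera with the preset correlation (adjusted p = 0.0155) and did not pass with an estimated correlation (adjusted p = 0.558, unadjusted p = 0.062). None of its members passed over all genes and 0 passed when adjusted over the list alone. The camera call was lost without Il10-/- replicate 3 (adjusted p = 0.125) or 4 (0.0514), without Il10+/+ replicate 1 (0.0564) or 4 (0.104), and without both arrays that stood apart (0.0633). The difference did not shrink in that last case, where the mean of the members was 0.36 (SE 0.22) in 6 arrays, against 0.36 (SE 0.16) in all 8.

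Ribosomal protein genes formed the third group that was higher by camera, with a median of 0.14 and a positive difference in 10 of 14 members (adjusted p = 0.0159 with the preset correlation, and adjusted p = 0.558, unadjusted p = 0.0781, with an estimated correlation). Rps7 differed by 0.54 (0.35 without Il10+/+ replicate 4) and Rps15 by 0.36, while Rpl38 and Rps19 differed by 0.02 and 0.06, and 0 members passed over all genes or adjusted over the list alone. The call was lost without Il10-/- replicate 3 (adjusted p = 0.114, median 0.09) or 4 (0.105) and without Il10+/+ replicate 4 (0.155, median 0.03). These 3 groups were the only ones of 24 past the threshold by camera with the preset correlation, and 0 of 24 passed with an estimated correlation, where 0.062 was the smallest unadjusted p, or by fry in one direction or either.

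**Figure D3:**
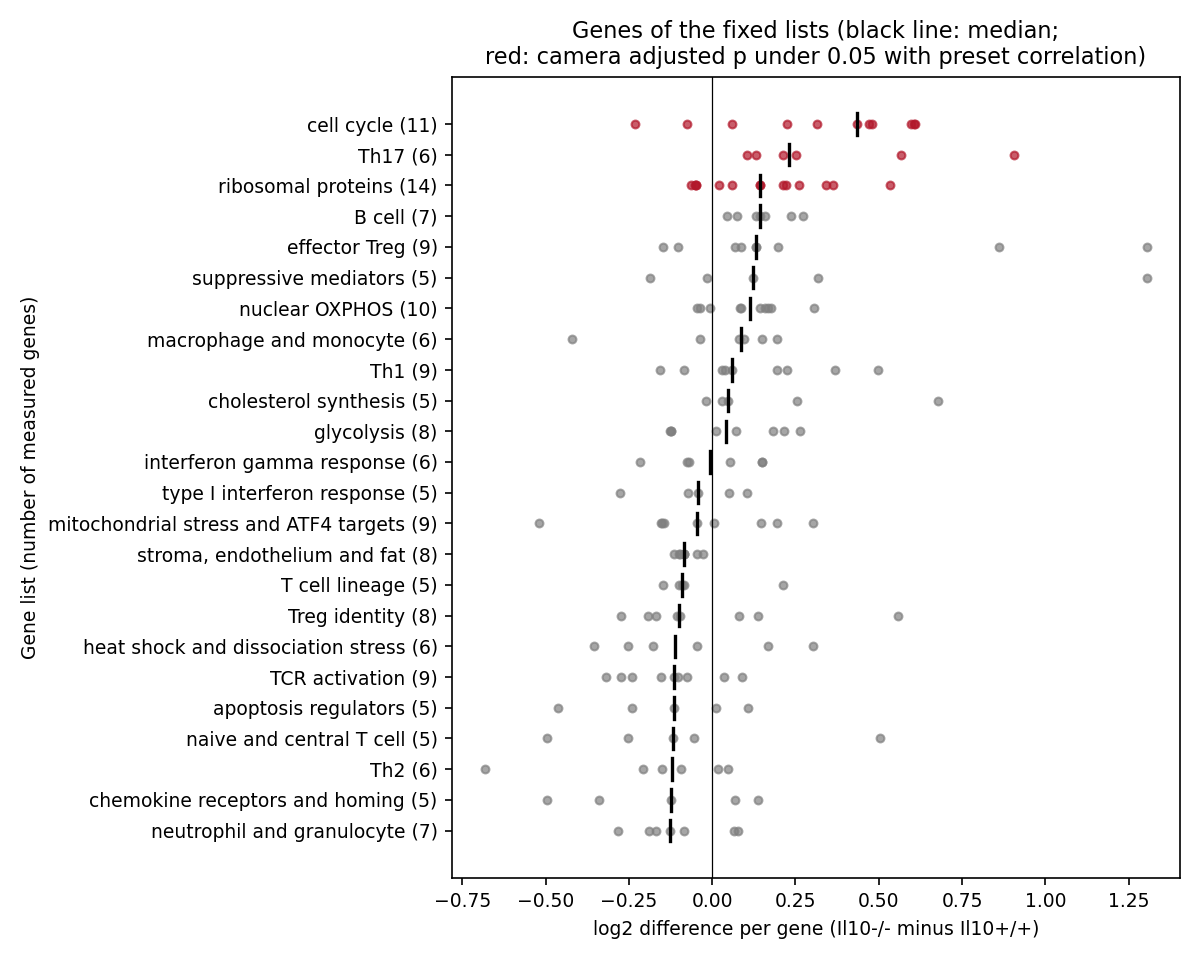
Log2 difference per gene (x axis, Il10-/- minus Il10+/+ as labelled) for the 24 tested gene lists (y axis, number of measured genes in brackets), with a black line at each median and red points for lists past adjusted p of 0.05 by camera with the preset correlation. The cell cycle, Th17 and ribosomal protein lists have the 3 highest medians, at 0.43, 0.23 and 0.14.

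The lists of regulatory T cell and naive T cell genes did not pass camera. The 8 measured Treg identity genes had a median of -0.10 and a mean of -0.01 (adjusted p = 0.709), with Socs2, a feedback inhibitor of cytokine signalling, at 0.56 (0.33 without Il10+/+ replicate 4, and -0.05 by its dimmer probe set) and Ikzf2 at -0.19. Effector Treg genes had a median of 0.13 (adjusted p = 0.0763). Among them the checkpoint receptor gene Havcr2 differed by 0.86 (SE 0.27) and the granzyme gene Gzmb by 1.30 (SE 0.50), with Gzmb at 9.41 ± 0.45 against 8.10 ± 1.24 (SD, n = 4 each). Suppressive mediators had a median of 0.12 (adjusted p = 0.279), with Lgals1, which encodes galectin-1, at 0.32. Naive and central T cell genes had a median of -0.12 (adjusted p = 0.705), and of these the homing receptor gene Ccr7 differed by -0.49 (-0.33 without Il10-/- replicate 2, -0.32 without Il10+/+ replicate 3) and Ramp1 by 0.50. Ramp1 passed when adjusted over the list alone, and no gene of the other 3 lists did. With Il10-/- replicate 2 or Il10+/+ replicate 2 left out, the effector Treg list passed camera as higher (adjusted p = 0.00728 and 0.00085), as did suppressive mediators (0.0407 and 0.00289), and the effector list also passed with array weights (0.00842). Gzmb belongs to both lists, so their calls are not independent. It read 9.88 in Il10+/+ replicate 2, above every array labelled Il10-/-.

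Among T helper genes, Ifng, which encodes interferon gamma, was at 7.84 ± 0.18 in the arrays labelled Il10-/- and 7.34 ± 0.03 in those labelled Il10+/+ (SD, n = 4 each). The difference was 0.50 (SE 0.11) without overlap (exact permutation p = 0.0286, the smallest possible). Ifng passed when adjusted over the Th1 list alone but not over all genes (limma, adjusted p = 0.406). The 9 Th1 genes together had a median of 0.06 (adjusted p = 0.170), with the chemokine gene Ccl3 at 0.37 (0.24 without Il10-/- replicate 1, 0.20 without Il10+/+ replicate 1) and the Th1 regulator Tbx21 at 0.03. The 6 Th2 genes had a median of -0.12 (adjusted p = 0.143), with the cytokine gene Il13 at -0.21 and the receptor gene Il17rb at -0.68 (SE 0.21), and Il17rb passed when adjusted over the list alone. The Th1 list passed camera as higher without Il10+/+ replicate 2 (adjusted p = 0.0318), and the Th2 list as lower without Il10-/- replicate 2 (0.0407) and with array weights (0.0469). Of the follicular helper genes, Slamf6 differed by 0.20 and Il4 by -0.09. Of the 4 measured genes of the IL10 receptor and STAT3 pathway, Osm differed by -0.21, Il6st by -0.16, Stat3 by -0.10 and Socs3 by 0.055.

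The lists of interferon, activation, survival and homing genes did not pass camera. Type I interferon response genes had a median of -0.04 (adjusted p = 0.842; Stat2 at -0.28, Phf11b at 0.11) and interferon gamma response genes one of -0.01 (adjusted p = 0.901; Wars at -0.22, Irgm1 at 0.15). T cell receptor activation genes had a negative difference in 7 of 9 members and a median of -0.11 (adjusted p = 0.105), with the NF-kappaB inhibitors Tnfaip3 at -0.32 and Nfkbia at -0.15. Apoptosis regulators had a median of -0.11 (adjusted p = 0.221), with the survival gene Bcl2 at -0.24 (-0.07 by its dimmer probe set) and the death receptor gene Tnfrsf10b at -0.46 (-0.21 without Il10-/- replicate 3). Chemokine receptors and homing genes had a median of -0.12 (adjusted p = 0.376), with Cxcr4 at -0.34 (-0.13 without Il10-/- replicate 2, -0.15 without Il10+/+ replicate 2). The T cell receptor activation list passed as lower without Il10-/- replicate 1 (adjusted p = 0.0228) or Il10+/+ replicate 4 (0.0494). No member of these 5 lists passed over all genes or adjusted over the list alone.

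Metabolic and stress genes likewise did not pass as groups. Nuclear OXPHOS genes had a median of 0.11 (adjusted p = 0.159; Ndufb3 at 0.30 and 0.16 without Il10+/+ replicate 2, Cyc1 at 0.17), and glycolysis genes one of 0.04 (adjusted p = 0.842; Hif1a at 0.22 and 0.16 by its 2 probe sets, Aldoc at 0.18). Cholesterol synthesis genes had a median of 0.05 (adjusted p = 0.170), with Sqle, squalene epoxidase, at 0.68 (SE 0.19), which passed when adjusted over the list alone, and Hmgcs1 at 0.25. Mitochondrial stress and ATF4 target genes had a median of -0.05 (adjusted p = 0.928), with the chaperonin gene Hspe1 at 0.30 (0.17 without Il10+/+ replicate 2) and the stress-induced gene Ddit4 at -0.52 (-0.31 without Il10-/- replicate 2, -0.30 without Il10+/+ replicate 2). Heat shock and dissociation stress genes had a median of -0.11 (adjusted p = 0.901), with the chaperone gene Hsp90aa1 at 0.17. In the other 4 of these lists 0 genes passed when adjusted over the list alone, and none of the 5 had a gene past the threshold over all genes. Without Il10-/- replicate 2, the OXPHOS list (adjusted p = 0.00365) and the cholesterol list (0.0323) passed camera as higher, and the OXPHOS list also did so with array weights (0.0469).

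Marker lists of T cells and of other cells that a sort of CD4+CD25+ cells can carry over did not pass camera either. T cell lineage genes had a median of -0.09 (adjusted p = 0.549; Themis at 0.21, Ptprc at -0.09). The 7 B cell genes were all positive, with a median of 0.14 (adjusted p = 0.120), Cd79b at 0.27 and Vpreb3 at 0.24. By camera with an estimated correlation, the B cell list had an unadjusted p of 0.0667 (adjusted p = 0.558). That lay between the unadjusted p of Th17 (0.062) and of ribosomal proteins (0.0781). Macrophage and monocyte genes had a median of 0.09 (adjusted p = 0.901; Lyz1 at -0.42 and -0.22 without Il10+/+ replicate 1), neutrophil and granulocyte genes one of -0.13 (adjusted p = 0.293; Cxcr2 at -0.19, Fcer1a at -0.28), and the 8 genes of stroma, endothelium and fat were all negative with a median of -0.09 (adjusted p = 0.143; Col3a1 at -0.09, Dcn at -0.10). Of lists too short to test, Batf3 of dendritic cells differed by 0.28, the plasma cell genes Derl3 and Sdc1 by 0.17 and -0.11, Itga2 and Fcgr3 of NK cells by 0.23 and 0.08, and Slc4a1 and Itga2b of red cells and platelets by 0.10 and 0.05. In these lists 0 genes passed over all genes or adjusted over the list alone. The stroma list passed as lower without Il10-/- replicate 2 (adjusted p = 0.0407), and the B cell list as higher with the mean of a gene's probe sets (0.0453).

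Ctse lies close to Il10 on chromosome 1, with 8 tested genes between them. A stretch of chromosome of another strain can stay with a targeted gene through backcrossing, so genes near Il10 were compared with all others. Within 10 Mb of Il10, Ctse was the 1 called gene of 154, against 1 of 6787 elsewhere, Efcab2, which lies 408 tested genes from Il10 (Fisher's exact test, two-sided, p = 0.0439). At an unadjusted p under 0.01, 5 of 154 genes near Il10 (3.25%) and 81 of 6787 others (1.19%) were counted (Fisher's exact p = 0.0418). The 5 were Ctse, Atp2b4 at 0.59, Rnpep, an aminopeptidase gene, at -0.51, the troponin gene Tnnt2 at -0.60 and Lad1 at -0.69. Lad1 and Tnnt2 were adjacent tested genes, at places 78 and 79 from Il10, with Rnpep at 69, and all were lower. Atp2b4, at place 43, was higher. Fisher's exact test counts such neighbours as independent genes. The result rested on Ctse, since without it 4 of 153 genes remained (2.61%, Fisher's exact p = 0.118). With called genes, Fisher's exact test also missed the threshold in a window of 20 Mb (p = 0.0557) and without Il10-/- replicate 3 (p = 0.0859). Since Ctse was the 1 called gene inside, these p-values depend only on the window's share of genes and on how many genes were called elsewhere.

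**Figure D4:**
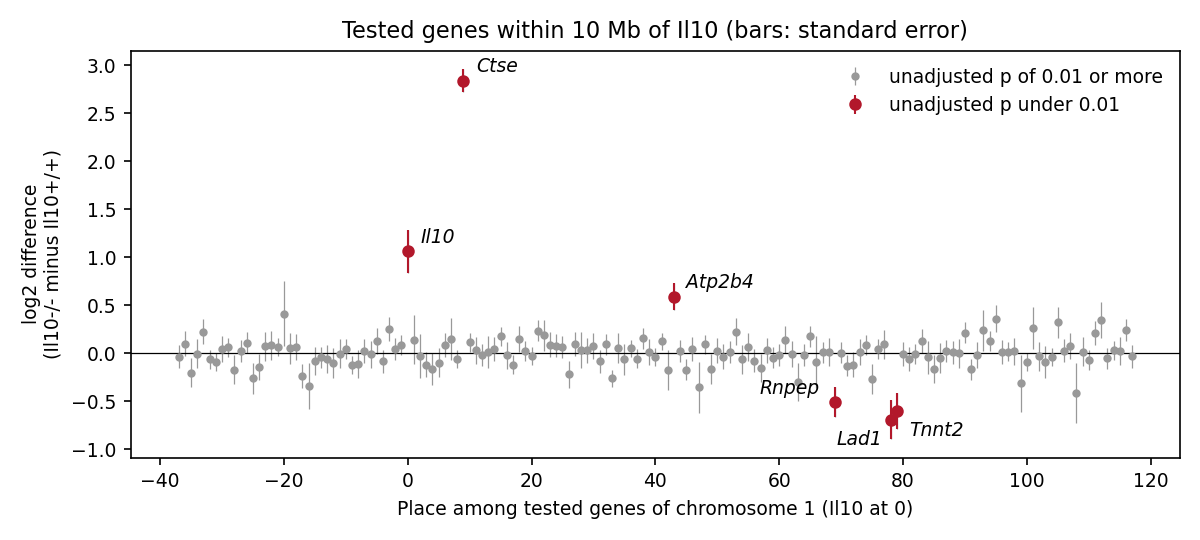
Log2 difference (y axis, Il10-/- minus Il10+/+ as labelled) of each tested gene within 10 Mb of Il10, by its place among the tested genes of chromosome 1 (x axis, Il10 at 0), with bars for the standard error. Ctse stands at 2.84 and Il10 at 1.06, and the genes at unadjusted p under 0.01, in red, have differences of either sign.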

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

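In this part, the tests of the strain segment, the probe variant, other cells, the arrays that stood apart, exchanged labels, STAT3 feedback and genes that vary together, the split counts per list and by the place of the arrays that stood apart were chosen only after the results were seen. The split counts of all called genes and lists, camera with an estimated correlation and leaving out single arrays were planned, though the use of that camera test for genes that vary together was not. Of 140 groups of 4 arrays examined, 8 held an array far from the other 3, where chance gives about 7. Il10-/- replicate 2 was the array in 4 of them, and it is also 1 of the arrays that stood apart. In that array Ctla4 read 10.88 (others 11.29 to 11.36), Ctse 11.49 (others 11.72 to 11.75), Ctla2b 7.99 (others 7.03 to 7.18) and Ddit4 7.34 (others 8.16 to 8.19). In Il10-/- replicate 3, Socs2 read 9.03 (others 8.35 to 8.44) and Hif1a 11.04 (others at 11.12). Efcab2 read 6.79 in Il10+/+ replicate 2 (others at 6.87), and Derl3 read 6.71 in Il10+/+ replicate 1 (others 7.16 to 7.21).

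Ctse was 2.84 higher on the log2 scale in the arrays labelled Il10-/-. Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, gave as many called genes (2, highest other 0). The 2 were Ctse and Efcab2. A share of 1 in 35 is the smallest these splits can give, so a chance assignment is unlikely for this count but not excluded. Leaving out both arrays that stood apart left 2.89 (limma, adjusted p = 4.26e-05, range over the alternatives 1.75e-07 to 0.00164). B cells, macrophages, granulocytes or stromal cells would have brought their own transcripts, but the highest difference among their 28 markers was 0.27, for Cd79b. It was 0.45, for Fcer1g, without Il10+/+ replicate 3. A small share of such cells is not excluded, since some markers were dim in both groups, such as Dcn (means 5.05 in Il10-/- and 5.15 in Il10+/+). Nor are B cells present in both groups alike, since their gene Ighm was bright in each, as given under Other observations. Dendritic cells, red cells and platelets, plasma cells, and CD8 T and NK cells stay open, with 1, 2, 3 and 4 measured markers. A stretch of chromosome from another strain carried with the targeted gene remains a candidate explanation, because 4 of the 153 other genes near Il10 were at unadjusted p under 0.01, too few to decide (Fisher's exact p = 0.118). It cannot be told apart from an effect of Il10 loss, nor can a strain variant under the probes that lowers the donor allele's signal, which would give a difference below 0, since with all labels exchanged the value would be -2.84, and the oxytetracycline given to these mice stays open too, untested.

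The Il10 signal was 1.06 higher in the arrays labelled Il10-/-. The 2 arrays that stood apart are not the source, since without them the difference was 1.04 (limma, adjusted p = 0.0678, range over the alternatives 0.0029 to 1.00). An exchange of all labels cannot be told apart from correct labels by the difference of 1.06, nor an exchange of single arrays by Ctse, in which 8 of 8 arrays lay outside the other group's range, because Ctse was picked as a gene that separates the arrays. A mutant transcript that still carries the sequence read by the probe set, made at a higher rate without interleukin 10 feedback, may be an explanation. Socs3, which STAT3 induces, differed by 0.055 (SE 0.16), which does not decide it, and whether the probe set lies outside the mutated part stays open.

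The cell cycle, Th17 and ribosomal protein lists were higher in the arrays labelled Il10-/- by camera with the preset correlation, but 20 of the 35 splits gave 3 or more lists, with 10 in the highest other split, so chance cannot be excluded. All 15 splits with the 2 arrays that stood apart in the same group gave 3 or more, which points to a structure of the arrays besides the genotype, and among the 20 with them in different groups, as in the real one, 5 did, the real one included (25%). Genes that vary together between arrays may explain the calls of all 3 lists. By camera with an estimated correlation the unadjusted p was 0.231 for the cell cycle, which 14 of 35 splits called, and 0.062 for Th17, which 8 of 35 called. For ribosomal proteins it was 0.0781, and 5 of 35 splits called that list. Its estimated correlation was lower, 0.11 against 0.65 for the cell cycle and 0.22 for Th17, but still above the preset 0.01. Without both arrays the mean of the members hardly moved, from 0.36 (SE 0.16) to 0.36 (SE 0.22) for Th17, whose call ended with 6 arrays and a wider error (camera, adjusted p = 0.0633), and from 0.32 (SE 0.22) to 0.30 (SE 0.26) for the cell cycle, which passed (0.0464), but leaving out Il10+/+ replicate 4 alone ended all 3 calls (0.231 for the cell cycle, 0.104 for Th17 and 0.155 for ribosomal proteins) and leaving out Il10-/- replicate 2 alone gave 9 lists, so the part played by these arrays stays open. A difference by genotype stays open, untested beyond the comparison itself.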

How the results depend on the processing

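Ctse passed in all alternatives run, with differences of 2.80 to 2.90 and, with 1 array left out, 2.76 to 2.91 (limma, adjusted p = 2.95e-06 to 1.75e-05). The count of genes, 2 with 2 higher, became 1 with 1 higher with each array centred on its median, with array weights, by the t-test after adjustment, with all probe sets tested and without both arrays that stood apart, and 1 to 4 with 1 array left out. It was 4 without Il10-/- replicate 3, 2 without Il10-/- replicate 4 and 1 without any other array. The gene lost was Efcab2 (adjusted p = 0.0782, 0.0655, 0.466, 0.311 and 0.149 in that order, range over all alternatives 0.0147 to 0.466, and 0.000809 to 0.136 with 1 array left out), while its difference stayed at 1.30 to 1.35, and at 1.23 to 1.52 with 1 array left out. The t-test at unadjusted p gave 327 genes, 204 higher and 123 lower, which follows from its threshold, and in the other alternatives 0 genes were lower. No detection call was used, and leaving out dim genes by either filter left the count at 2. Hesx1, which both filters left out as dim, passed with trend and robust settings (adjusted p = 0.0454) and without Il10-/- replicate 3 (0.0399). Il10 passed by the t-test at unadjusted p (1.06) and with the spread of each array as a covariate (1.07, adjusted p = 0.0029), and its difference was 0.86 to 1.24 with 1 array left out.

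The count of 3 lists became 6 with array weights (effector Treg, Th2 and nuclear OXPHOS gained) and 0 by camera with an estimated correlation, camera on ranks and fry in one direction or either. It was 0 to 9 with 1 array left out: 0 without Il10-/- replicate 3 or 4, 1 without Il10+/+ replicate 1 (ribosomal proteins), 1 without Il10+/+ replicate 4 (TCR activation, not among the 3), 6 without Il10+/+ replicate 2 (effector Treg, suppressive mediators and Th1 gained) and 9 without Il10-/- replicate 2 (effector Treg, suppressive mediators, Th2, nuclear OXPHOS, cholesterol synthesis and stroma gained). Adjusted p was 2.9e-07 to 0.231 for the cell cycle, 0.00112 to 0.125 for Th17, 0.00152 to 0.155 for ribosomal proteins and 0.00085 to 0.27 for effector Treg. Fisher's exact p near Il10 was 0.0557 at 20 Mb, 0.118 at unadjusted p with Ctse left out, and 0.0222 to 0.0859 with 1 array left out. Whichever array was left out, Ctse was the 1 called gene inside. The range with 1 array left out therefore follows from how many genes were called elsewhere, and does not measure how stable the neighbourhood result is. None of the 3 called lists turned direction. Of the uncalled lists, 10 turned with 1 array left out, where adjusted p was 0.27 to 0.986 for Treg identity, 0.231 to 0.986 for naive T cell, type I interferon and homing genes, 0.15 to 0.903 for interferon gamma response, 0.333 to 0.964 for glycolysis, 0.752 to 0.986 for ATF4 targets, 0.412 to 0.954 for heat shock, 0.324 to 0.954 for T cell lineage and 0.364 to 0.992 for macrophage. In other alternatives 6 lists turned, none past the threshold (adjusted p): with array weights Treg identity (0.851), interferon gamma response (0.834), ATF4 targets (0.931), heat shock (0.939) and macrophage (0.612); without both arrays that stood apart ATF4 targets (0.937), heat shock (0.896) and macrophage (0.383); by fry interferon gamma response (0.996) and ATF4 targets (0.989); with arrays centred ATF4 targets (0.985); and without the dimmer genes glycolysis (0.993). Of 67 named genes besides Il10, 0 turned in other alternatives and 4 with 1 array left out: Ctla4 (-0.15 to 0.0070), Il4 (-0.21 to 0.014), Irgm1 (-0.018 to 0.26) and Itga2b (-0.016 to 0.11). Of the 65 uncalled ones, 38 moved by over 1.5 times with 1 array left out, 12 of them with a difference of 0.30 or more in size. The cause was not tested for any of these changes. The alternatives without both arrays, with the spread as a covariate and with Ctse left out were chosen after seeing the data.

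The replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at 0.05, -0.32, 0.03 and -0.19, and 0 of 8 arrays correlated best with their own number. With the replicate block, 1 gene passed, Ctse, which was higher, and Efcab2 had an adjusted p of 0.0689 by limma. The Il10 difference was 1.06, and 3 lists passed. Fisher's exact p near Il10 was 0.0222, which follows from Ctse being the 1 called gene.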

Other observations

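In this part, the looks at Ighm and Icos, the tests around Efcab2 and over chromosome 1, the reading of ATF4 targets as a trace of oxytetracycline and the count of one-sided splits were chosen only after the results were seen. The split count near Il10, the test of all probe sets and camera on the ATF4 list were planned. Ighm, the heavy chain of immunoglobulin M, which B cells make in abundance, read 12.13 ± 0.44 in the arrays labelled Il10-/- and 11.97 ± 0.29 in those labelled Il10+/+ (SD, n = 4 each). The inducible costimulator Icos read 11.74 ± 0.09 and 11.61 ± 0.08. Among probe sets without a gene name, 0 passed the threshold when all probe sets were tested. The 2 with the smallest p were 17203901, with a log2 difference of 1.39 (limma, adjusted p = 0.167), and 17284442, with 7.96 against 5.61, a difference of 2.36 (adjusted p = 0.232).

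Near Il10, 1 of the 35 splits, the real one, gave a called gene inside the window (1, highest other 0). Because the other splits called 0 genes anywhere, this follows from the gene count and says nothing more about the window. Efcab2 is also on chromosome 1, and a second carried segment could be behind it, but 9 of 206 other genes within 10 Mb of it (4.37%) were at unadjusted p under 0.05, against 322 of 6735 elsewhere (4.78%, Fisher's exact p = 1), a comparison with too few genes to exclude it. On chromosome 1 as a whole, 20 of 1221 genes (1.64%) were at unadjusted p under 0.01, against 66 of 5720 (1.15%) on the others (Fisher's exact p = 0.198). Oxytetracycline, which inhibits mitochondrial translation, might raise ATF4 targets in the mice that drank it, but the list did not pass camera (adjusted p = 0.928), and with 9 measured genes this does not decide it. The excess of higher over lower genes at unadjusted p under 0.05 lay 16.8 percentage points from even, and 6 of the 35 splits were as one-sided, up to 25.7, so chance cannot be excluded for it.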
